A study of Mus musculus with 2 samples.

How the data were processed

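The series holds 2 Visium CytAssist libraries, 1 from a section of a B16.F10 melanoma grown in a WT mouse and 1 from a tumour grown in a KO mouse. Per the labels, the mice were 8 to 16 weeks old, the tumours were of similar size, and sections of 10 µm were cut from formalin-fixed, paraffin-embedded tissue. Genotypes were taken from the sample labels, and nothing in the values was used to assign a group.

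For each section the authors deposited a matrix of UMI counts per gene and spot, made with Space Ranger 2.1.0 per the file headers and holding 19465 genes. The submitters' processing notes name Space Ranger, featureCounts and the mm10 build, with no role for each. The counts are whole numbers and are not normalized, and the matrices hold spots under tissue. A grid of 4992 positions per section gives each spot's row and column and whether it lies under tissue, per the file headers. The authors also deposited a spatial table per section, with Moran's I for each gene, a score computed by their software on its own normalized counts, per the file headers. The deposited p-value and adjusted p-value columns of that table compare a gene's layout within 1 section and were not used here. Its deposited signal column, a mean over spots of counts scaled to the median spot, was not used either. Image scale factors and alignments were not used. Only Moran's I was taken from the spatial table, and no value of it was recomputed.

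UMIs of each gene were summed over all spots of a section and scaled to the section's total (CPM). The KO over WT ratio of each gene carries an exact conditional binomial (Clopper-Pearson) interval at 95%. A replicate-based test needs more than 1 section per genotype, so no p-value, standard error or call of changed genes was computed, and spots were never used as replicates. Each section was split at its median spot row and column into 4 quadrants, whose range shows the spread inside 1 section.

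Gene lists, 33 in number with 420 genes of which 397 are in the matrix, were written before the data were examined, together with the comparisons, the rule for named genes and the alternative settings other than those said to be added later. A list member was measured with at least 50 UMIs over both sections. For each list the median of log2 ratios, with 0.5 added to each count, was set against 10000 random lists of the same size drawn from 20 bins of mean expression. Its interval comes from 1000 Poisson redraws of the counts. The percentile among random lists describes these 2 libraries and is not a test of genotype. Xist and Lilrb4a were not analysed here.

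Genes were named by a fixed rule. Among genes with at least 500 UMIs in the section where they have more, the 12 highest and 12 lowest ratios could be named, leaving out symbols of predicted genes. Csnk2b, Csnk2a1, Csnk2a2, Foxp3, Cd8a, Cd8b1, Cd3e and Cd4 were always reported. Of each list the 3 members with the most UMIs and those with the highest and lowest ratio could be named. The 8 genes with the highest Moran's I in a section and the 5 leading genes of a region could be named too. Genes picked after their values were seen are said to be so where they appear: Cxcl9, Gbp4, Gbp5, Bnip3, Vegfa, Hk2, Azin2, Odc1 and Gzmb. Gene positions come from the RefSeq annotation of GRCm38, the assembly that mm10 denotes, and give the whole gene.

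Probes give some UMIs for genes that a tissue does not express. A list of 15 genes of pancreas, testis, retina, kidney, liver, heart and pituitary served to measure this. Their median count was taken off each gene as an added alternative, over members above 2 times that background in a section.

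To compare shares of spots, each spot was thinned at random to 5000 UMIs, and spots below that depth were left out. This left out 395 WT and 356 KO spots, so shares describe the deeper spots. Shares carry exact binomial intervals. Spots with and without Cd8a or Cd8b1 were compared within a section, and these 2 genes were left out of the lists for that step. Rim spots lie within 2 steps on the hexagonal grid of a position without tissue or of the frame of the capture area, giving 1364 rim and 1702 interior spots in the WT and 761 and 1985 in the KO section. Melanocytic-rich spots are those at or above the median share of UMIs from melanocytic genes, taken over the spots of both sections.

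Regions were found in each section by itself with scanpy 1.11.5, using counts per 10000 UMIs on a log scale, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5. A region's leading genes have the highest CPM over the rest of the section among genes with at least 20 CPM in it. Regions were not matched or compared in size between genotypes, and no spot was assigned a cell type. No deconvolution was run.

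The alternatives were scaling by edgeR TMM factors (0.927 for WT and 1.08 for KO, edgeR 4.0.16 in R 4.3.3), by median-of-ratios size factors or by the total without the 50 most abundant genes. Others gave each spot equal weight, or used spots with at least 5000 UMIs, interior spots, or melanocytic-rich spots. Equal weight counts a shallow spot, down to 66 UMIs in the WT and 293 in the KO section, as much as a deep one. Values under it can therefore rest on few UMIs. Limits on list members, thinning depth, neighbour distance, rim width, bins and clustering settings were varied as well, and both sections were clustered together with each gene centred within its section. Other work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

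The steps were tested on simulated data. For the gene ratios of KO over WT, counts were drawn for 10180 genes with 100 genes changed 2-fold and 100 genes changed 4-fold. The median estimates were 2.00 and 4.01, and 96.0% of intervals held the truth at each size. Of the 9980 unchanged genes 95.2% had intervals that held 1, and 0 passed 2-fold. A pan T cell list changed 2-fold, among 16961 genes, gave a median log2 ratio of 1.01 at percentile 100, and an unchanged one gave -0.04 at percentile 14.4. Thinning kept a gene's mean share of a spot's UMIs at 1.00 of its unthinned value, as the median over 452 genes. This is not the share of spots with a UMI, which falls with depth. A 3-fold rim in the 16 pan T cell genes was recovered as 2.96 in the WT and 3.03 in the KO grid.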

Results

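Gene expression was mapped in 2 tumour sections with Visium CytAssist, a method in which pairs of gene-specific probes are ligated on fixed tissue and moved onto a grid of barcoded capture spots, each of which can hold several cells. The tumours were grown from B16.F10, a pigmented mouse melanoma line, and taken on day 15 after inoculation. The WT section came from a mouse carrying floxed Csnk2b without Cre. The KO section came from a mouse in which Foxp3-driven Cre removes Csnk2b from regulatory T cells, the CD4 T cells that restrain other immune cells. Csnk2b encodes the regulatory subunit of protein kinase CK2. The WT section had 3066 spots under tissue and 88735936 unique molecular identifiers (UMIs), with medians of 26818.5 UMIs and 6665 genes per spot. The KO section had 2746 spots and 94422680 UMIs, with medians of 36769 UMIs and 7480 genes per spot. With 1 section per genotype no difference between them has a replicate check, so values are given for both sections with 95% intervals that cover counting error only. Spread within a section is given as the range over its 4 quadrants.

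The comparison asks how a melanoma differs when its host's regulatory T cells lack CK2 beta. The target gene was measured first. Csnk2b (chromosome 17, 35116195 to 35122053 in GRCm38) stood at 392 CPM, its count scaled to the section's total UMIs, in both sections, a KO over WT ratio of 0.998 (0.984 to 1.01), or 0.858 when TMM factors set the scale. Tumour cells and all other host cells keep Csnk2b by design, so this sum does not check the deletion in regulatory T cells. Csnk2a1, a catalytic subunit, was 1.45-fold higher in the KO section (1.42 to 1.48). Csnk2a2, the other catalytic subunit, had a ratio of 1.16, which became 0.994 with TMM factors. The 3 CK2 subunit genes had a median log2 ratio of 0.21, which TMM factors brought to -0.01. Foxp3 (chromosome X, 7579676 to 7595243), the transcription factor that defines regulatory T cells, gave 32 UMIs in the WT and 51 in the KO section. Its ratio of 1.498 (0.944 to 2.41) includes 1, and both counts lay below 2 times the probe background. That background was read from 15 genes of other tissues, such as insulins and protamines, which had a median of 22 UMIs in the WT and 49 in the KO section, a 2.09-fold difference in CPM. A low count can therefore be higher in the KO section without expression of the gene.

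T cell genes were higher in the KO section, as were erythroid and skeletal muscle genes, with median log2 ratios of 2.73 and 2.43. All 16 pan T cell genes had a ratio above 1 and 14 of them were at least 2-fold higher, with a median log2 ratio of 1.41 (1.28 to 1.61) that exceeded all 10000 random lists of matched expression. Cd3e, a chain of the T cell receptor complex (chromosome 9, 44998735 to 45009663), was 3.62-fold higher (3.15 to 4.18). Trac and Trbc2, the constant regions of the receptor, were 2.504-fold and 2.11-fold higher, and Cd5 gave 32 and 165 UMIs, the WT count below 2 times the background. Lck, the kinase that starts receptor signalling, was the lowest member at 1.42-fold, and its ratio was 0.895 among interior spots.

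Cytotoxic genes followed the same direction. The 14 genes of the CD8 and cytotoxic list all had ratios above 1, 10 of them at least 2, with a median log2 ratio of 1.40 (1.22 to 1.60) above all random lists. Cd8a, the CD8 coreceptor (chromosome 6, 71373427 to 71379171), had 140 UMIs in the WT and 606 in the KO section, a 4.07-fold difference (3.38 to 4.92). The 4 KO quadrants held 3.44 to 10.9 CPM of Cd8a and the WT quadrants 0.743 to 2.95. Giving each spot equal weight, however few its UMIs, lowered the Cd8a ratio to 1.96. With counts summed over spots of at least 5000 UMIs it was 4.06. Cd8b1, the second chain of the coreceptor, was 2.59-fold higher (2.09 to 3.23), with 1.73 among interior and 4.95 among melanocytic-rich spots. Gzma, a granzyme released by killer lymphocytes (chromosome 13, 113093824 to 113100981), was 11.9-fold higher (9.44 to 15.2), with 5.96 at equal weight per spot and 24.2 in melanocytic-rich spots, and the T cell chemokine Ccl5 2.37-fold. Ccl5 held 50.5 of the list's 60.3 CPM in the WT and 119.5 of 159.1 CPM in the KO section, so summed values of this list by quadrant, rim or region mainly read Ccl5. Klrk1, the activating receptor NKG2D, had a ratio of 1.20 (0.829 to 1.75), and 0.629 with equal weight per spot.

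**Figure D1:**
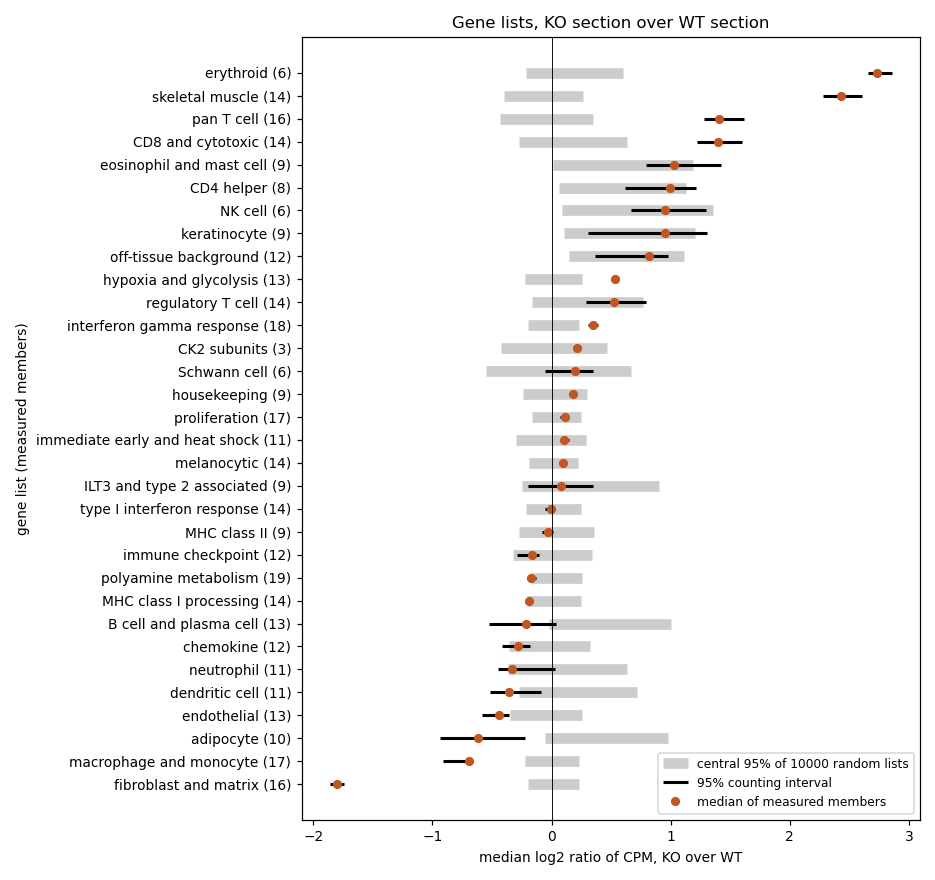
Median log2 ratio of KO over WT CPM for 32 gene lists (points, x axis), with lists and their numbers of measured genes on the y axis, 95% counting intervals as black lines and the central 95% of random lists as grey bars. Pan T cell (1.41), CD8 and cytotoxic (1.40), skeletal muscle (2.43) and erythroid (2.73) genes lie to the right of their bars, and fibroblast and matrix (-1.80) and macrophage genes (-0.69) to the left.

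The helper and regulatory T cell lists did not stand apart from matched genes. The CD4 helper list had a median log2 ratio of 0.99 at percentile 93.0 of its random lists, -0.08 after the background was taken off and -0.05 over members with at least 200 UMIs. Cd4 itself was 1.56-fold higher (1.24 to 1.96), with a ratio of 1.01 among interior spots and 2.502 with equal weight per spot. The regulatory T cell list had a median of 0.52 (0.29 to 0.80) at percentile 83.9, and 0.02 with the background taken off. Within it Tnfrsf9, a costimulatory receptor, was 1.99-fold higher (3.17-fold in melanocytic-rich spots), while Klrg1, a receptor of differentiated T cells, gave 162 UMIs in the KO section and 25 in the WT section, near the background there. Tnfrsf18, which encodes GITR, had a ratio of 0.720 (0.618 to 0.839). Lilrb4a, the gene of ILT3 itself, was not analysed. The list of ILT3 and type 2 associated genes was mixed, with a median of 0.08 that TMM factors turned to -0.14. It was -0.51 with the background taken off, -0.71 over members with at least 200 UMIs, -1.27 for summed CPM and 0.84 with equal weight per spot. Il33, an alarmin of stromal and epithelial cells, was 3.92-fold lower in the KO section (3.69 to 4.17). Its ratios were 0.629 at equal weight per spot and 0.668 in melanocytic-rich spots. The type 2 cytokine Il5 gave 35 and 101 UMIs, the WT count below 2 times the background. Immune checkpoint genes had a median of -0.17 at percentile 12.7, which was 0.09 in melanocytic-rich spots and -0.43 with the background taken off. Vsir, which encodes VISTA, was 2.71-fold lower (a ratio of 0.603 in melanocytic-rich spots) and Cd274, which encodes PD-L1, 1.52-fold higher.

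The NK cell and the eosinophil and mast cell lists rested on few UMIs. The NK cell list had a median of 0.95 at percentile 70.7, and 1.70 in melanocytic-rich spots, with 42 and 138 UMIs of Klre1. The eosinophil and mast cell list had a median of 1.03 at percentile 90.2, with the mast cell protease Cma1 3.19-fold higher from 56 and 190 UMIs, and 9.57-fold among interior spots. The neutrophil list had a median of -0.34 at percentile 3.205, which was 0.62 with equal weight per spot and 0.82 in melanocytic-rich spots. B and plasma cell genes had a median of -0.22 at percentile 0.605, 0.04 in spots rich in melanocytic transcripts, -1.33 with the background taken off, -0.91 over members with at least 200 UMIs and -0.98 for summed CPM. Of the 13 measured members of that list 3 were at least 2-fold lower, among them the joining chain Jchain with 286 and 23 UMIs. Outside this list, 2 antibody genes were among the 12 lowest ratios of genes with at least 500 UMIs in their higher section, the kappa light chain Igkc at 34.5-fold lower (28.8 to 41.6), with ratios of 0.0484 in melanocytic-rich, 0.0179 among interior spots and 0.0185 at equal weight per spot, and Igha with 1143 and 85 UMIs. The KO counts of Jchain and Igha lay below 2 times the probe background.

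Fibroblast and matrix genes were lower in the KO section. All 16 fibroblast and matrix genes had ratios below 1, 14 of them at least 2-fold lower, with a median log2 ratio of -1.80 (-1.86 to -1.75) below all random lists. Col1a1 (chromosome 11, 94936224 to 94953042), which encodes the main chain of type I collagen, was 10.4-fold lower, Col1a2 11.1-fold and Col3a1 6.28-fold. Within spots rich in melanocytic transcripts the list's median was -0.57, and the ratios of Col1a1, Col1a2 and Col3a1 were 0.278, 0.282 and 0.405. Among all genes with at least 500 UMIs in their higher section, the 12 lowest ratios included C1qtnf3 (30.8-fold lower), Cthrc1 (14.8-fold) and Lrrc15 (12.9-fold). They also included Mfap4 (12.5-fold), Fmod (12.03-fold) and Ccn3 (11.9-fold). Lrrc17 was 16.9-fold, Pcsk5 17.3-fold and Cdkn2b 11.7-fold lower. Ccl24, an eosinophil chemokine made by macrophages, was 11.3-fold lower, but had a ratio of 1.05 in melanocytic-rich spots. The KO counts of C1qtnf3, Pcsk5, Fmod, Cdkn2b and Ccl24 were at or below 2 times the probe background, so their ratios rest in part on that background. In melanocytic-rich spots the genes named here other than Ccl24 had ratios from 0.211 for C1qtnf3 to 0.708 for Fmod.

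All 17 measured macrophage and monocyte genes had ratios below 1, 8 of them at least 2-fold lower, with a median of -0.69 (-0.92 to -0.68) below all random lists. Trem2, a lipid receptor of tissue macrophages, was 3.92-fold lower (3.63 to 4.24), and the complement gene C1qa 1.29-fold. C1qa had a ratio of 1.18 with equal weight per spot and 0.477 among interior spots, where the list's median was -1.45. WT quadrants ranged from 571 to 3561 CPM for this list and KO quadrants from 377 to 2103 CPM, so the quadrants overlapped. The dendritic cell list had a median of -0.35 at percentile 1.265, with 236 and 52 UMIs of Cd209a. Endothelial genes had a median of -0.44 at percentile 0.885, with 12 of 13 members below 1 and Plvap 1.79-fold lower. In melanocytic-rich spots that median was 0.08 and the ratio of Plvap 0.851.

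The series title names polyamines, small polycations that cells make from ornithine. Of 19 measured genes of polyamine metabolism 15 had ratios below 1, and the median log2 ratio was -0.17 at percentile 2.58. It was -0.02 with equal weight per spot. Arg1 (chromosome 10, 24915207 to 24927470), which makes ornithine and is abundant in some macrophages, stood at 273 CPM in the WT and 24.4 CPM in the KO section, an 11.2-fold difference (10.7 to 11.7). In melanocytic-rich spots its ratio was 0.388 (2.57-fold lower). Oaz1, the antizyme that restrains ornithine decarboxylase, was 1.61-fold lower, and Atp13a2, a lysosomal polyamine exporter, 1.23-fold higher. Azin2, an antizyme inhibitor, was 5.002-fold lower, but had a ratio of 1.04 in melanocytic-rich spots. Odc1, which encodes ornithine decarboxylase, had a ratio of 0.774, and 1.007 with equal weight per spot. The last 2 genes were picked after their values were seen.

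Hypoxia and glycolysis genes were higher in the KO section. Of 13 measured genes 12 had ratios above 1, with a median log2 ratio of 0.53 (0.52 to 0.54) above all random lists. Car9, a carbonic anhydrase induced by low oxygen, was 2.78-fold higher (2.73 to 2.84) and the glucose transporter Slc2a1 1.501-fold. Bnip3, Vegfa and Hk2, the other 3 genes at least 2-fold higher, stood at 2.46-fold, 2.25-fold and 2.22-fold and were named after their values were seen. Egln3 was 1.81-fold lower, and 1.59-fold higher in melanocytic-rich spots. The list held 1793 to 2661 CPM in the WT quadrants and 2898 to 4731 CPM in the KO quadrants.

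Interferon gamma response genes split. Their median log2 ratio was 0.35 (0.31 to 0.39) at percentile 99.9, with 11 members above and 7 below 1, but their summed CPM had a ratio of 0.9496 and the median was -0.15 among interior spots. The chemokine Cxcl10 had a ratio of 0.645 and Irf8 0.569 (0.935 in melanocytic-rich spots). Gbp2b, a guanylate-binding protein, gave 177 UMIs in the KO section and 24 in the WT section, near the background there, and its ratio was 1.99 among interior spots. Cxcl9, a chemokine that draws CXCR3-bearing T cells, was 5.26-fold higher (4.82 to 5.74), Gbp4 3.40-fold and Gbp5 2.05-fold, all 3 named after their values were seen. Among interior spots these 3 had ratios of 3.40, 2.23 and 1.35. The type I interferon list had a median of -0.00, and MHC class II genes -0.03 (-0.62 among interior spots), with the invariant chain Cd74 at 1.15 (0.986 with TMM factors and 0.661 among interior spots). MHC class I processing genes had a median of -0.19 at percentile 3.24, with H2-D1 1.61-fold lower. Chemokine genes had a median of -0.29 at percentile 4.74, and 0.53 with equal weight per spot. Cxcl13, which attracts B cells, gave 372 UMIs in the KO section and 15 in the WT section, below the background there. The monocyte chemokine Ccl8 was 2.76-fold higher (0.879 in melanocytic-rich and 1.36 among interior spots) and Ccl7 2.25-fold lower.

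TMM factors shifted every log2 ratio by -0.22, which is larger than the medians of the tumour cell, housekeeping, stress and Schwann cell lists. Melanocytic genes had a median of 0.09, turned to -0.12 by TMM factors, with the pigment enzyme Dct 1.27-fold higher and the melanosome protein Pmel at 0.775. Proliferation genes had a median of 0.11, turned to -0.11, with Mki67 at 1.43 and Cdk1 at 0.665. The housekeeping list had a median of 0.18, turned to -0.04, with Hprt at 1.61 and Actb at 0.644. The stress list of immediate early and heat shock genes had a median of 0.11, turned to -0.11, and the Schwann cell list 0.20, turned to -0.02. The off-tissue background list stood apart from these, with a median of 0.82 at percentile 77.6, and 0.60 with TMM factors.

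Genes of neighbouring tissue and of blood were among the highest ratios. All 14 skeletal muscle genes were at least 2-fold higher in the KO section, with a median log2 ratio of 2.43, but the median was 0.33 in melanocytic-rich spots. The fast myosin Myh4 was 36.5-fold higher, the calcium buffer Pvalb 14.7-fold, Mybpc2 8.03-fold, Atp2a1 7.73-fold, Tnnt3 7.65-fold, Ttn 7.28-fold and Tnnc2 7.09-fold. In melanocytic-rich spots Atp2a1 had a ratio of 0.791, Tnnc2 1.004 and Myh4 2.06. All 6 measured erythroid genes were at least 2-fold higher, with a median of 2.73, Hbb-bt 16.8-fold and Hbb-bs 7.17-fold higher. With equal weight per spot these 2 genes had ratios of 10.2 and 4.50. The complement gene C6 was 11.8-fold higher, with 2.80 in melanocytic-rich spots, 5.10 among interior spots and 24.3 at equal weight per spot. Adipocyte genes had a median of -0.62, and 0.70 among interior spots, 0.96 in melanocytic-rich spots and -2.11 with the background taken off. Keratinocyte genes had a median of 0.95 at percentile 83.4, and -0.99 after the background was taken off. The 4 Y-linked genes gave 0 UMIs in the WT section and 1477 in the KO section. That is at least 376-fold more by the counting interval, and 463-fold more against a limit of 3 counts over the WT section. Ddx3y alone gave 580. The labels used here do not state the sex of the mice.

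In all, 10374 genes had at least 500 UMIs in their higher section, of which 87 were at least 2-fold higher and 525 at least 2-fold lower in the KO section. The higher genes made up 14.2% of both. TMM factors gave 7.41% (59 and 737 genes) and interior spots 12.6% (101 and 698 genes). With equal weight per spot they made up 26.7% (141 and 387 genes), and in melanocytic-rich spots 40% (92 and 138 genes).

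**Figure D2:**
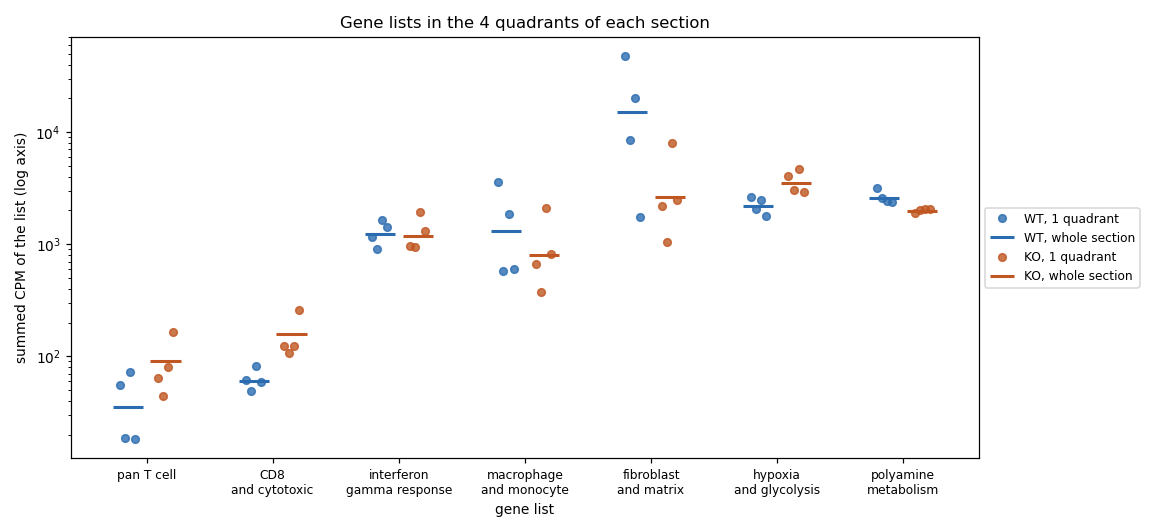
Summed CPM on a log axis (y) for 7 gene lists (x), with the 4 quadrants of the WT and KO sections as points and each whole section as a bar. CD8 and cytotoxic genes held 48.7 to 82.4 CPM in the WT quadrants and 107 to 260.3 CPM in the KO quadrants, while pan T cell (18.2 to 72.8 against 44.6 to 163.8) and fibroblast (1759 to 47454 against 1044 to 7919) quadrants overlapped.

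Spots with T cell transcripts were more frequent in the KO section. Every spot was thinned to 5000 UMIs to remove the difference in depth, which left out 395 WT and 356 KO spots. Cd8a was then detected in 17 of 2671 WT spots (0.636%, exact interval 0.371 to 1.02%) and 72 of 2390 KO spots (3.01%, 2.36 to 3.78%). Without thinning the shares were 4.34% and 15.5%. Cd3e was found in 1.72% and 5.65% of spots, Cd8b1 in 1.01% and 1.84%, and Cd4 in 0.599% and 1.76%. Any pan T cell gene was found in 16.7% of WT and 26.3% of KO spots. Foxp3 was found in 4 spots of each section (0.1498% and 0.167%), no more often than the median off-tissue gene (0.187% and 0.293%), and was not detectable above background at this depth.

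The study's design raises the question of where T cells lie relative to regulatory T cells. The 4 Foxp3 spots of each section were too few for a reading, with 0 of 4 in the WT and 2 of 4 in the KO section also holding Cd8a or Cd8b1. Spots with Cd8a or Cd8b1, 41 in the WT and 108 in the KO section, held more of most other immune lists, and in the KO section 9.60-fold more skeletal muscle and 5.53-fold more erythroid transcripts (0.0850 and 1.25 in the WT section). Any pan T cell gene was found in 51.2% of them in the WT section, against 16.1% of the other spots, and in 65.7% against 24.4% in the KO section. MHC class II genes, which present antigen to CD4 T cells, were 2.72-fold higher in these spots than elsewhere in the WT section (2.49 to 2.97) and 6.44-fold in the KO section (6.20 to 6.69). For the chemokine list these ratios were 2.00 and 3.99, and for the interferon gamma list 1.44 and 2.79. The off-tissue background list had 2.24 (1.06 to 4.19) and 1.26 (0.748 to 2.00), from 10 and 19 UMIs in such spots. WT ratios up to this size therefore do not stand apart from background. Of WT spots with a sparse off-tissue gene, 2 of 43 held Cd8a or Cd8b1 (4.65%, 0.568 to 15.8%), against 1.48% of other spots. In the KO section 7 of 65 did (10.8%, 4.44 to 20.9%), against 4.34%. Neighbours of such spots held Cd8a or Cd8b1 in 1.31% against 1.58% (WT) and 6.02% against 3.96% (KO). The WT values thus rest on 2 spots and point both ways. In spots with Cd8a or Cd8b1 the melanocytic list had ratios of 0.632 and 0.629. Hypoxia genes had ratios of 0.952 (0.867 to 1.04) and 0.522 (0.491 to 0.554).

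T cell and macrophage genes were concentrated at the rim of the KO section, as were skeletal muscle and fibroblast genes. The rim lies within 2 grid steps of an edge of the tissue or of the capture frame. It held 1364 spots in the WT section, against 1702 in the interior, and 761 against 1985 in the KO section. The rims thus cover unlike shares of the 2 sections, which limits a comparison of their ratios. Skeletal muscle genes had a rim ratio of 8.31 in the KO and 4.85 in the WT section. Fibroblast and matrix genes had 3.05 and 1.46, and melanocytic genes 0.819 and 0.994. Pan T cell genes were 2.82-fold higher in the rim than in the interior of the KO section (2.70 to 2.94) and 1.13-fold in the WT section (1.05 to 1.21). The WT ratio was 0.995 for a rim of 1 step. The CD8 and cytotoxic list was 2.13-fold higher in the KO rim and had a ratio of 1.02 (0.968 to 1.08) in the WT section. The rim ratio was 5.54 in the KO and 1.52 in the WT section for MHC class II genes, 4.96 and 1.24 for chemokines, and 4.62 and 1.45 for macrophage genes. In the interior alone the CD8 and cytotoxic list held 126 CPM in the KO section and 59.8 CPM in the WT section. The macrophage list held 439 CPM in the KO interior and 1129 CPM in the WT interior. Regulatory T cell genes had a rim ratio of 0.960 in the KO section (0.897 to 1.03) and 1.24 in the WT section. Tnfrsf9 held 27.6 of this list's 53.2 CPM in the KO and 13.9 of 35.9 CPM in the WT section. With Foxp3 below 2 times the background, these ratios do not place regulatory T cells.

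**Figure D3:**
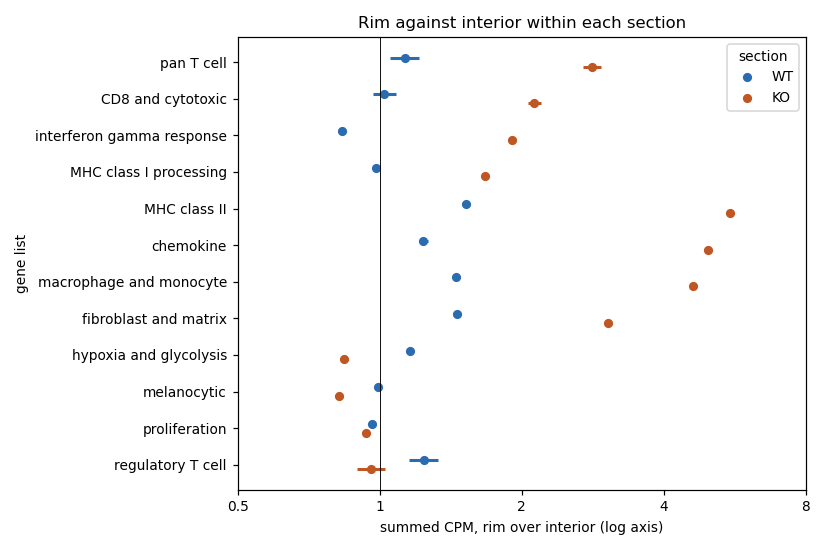
Summed CPM of the rim over the interior on a log axis (x) for 12 gene lists (y), with 95% counting intervals as lines, in the WT and KO sections. The KO section lies further from 1 than the WT section for MHC class II (5.54 against 1.52), chemokine (4.96 against 1.24) and pan T cell genes (2.82 against 1.13). The rim is a larger part of the WT section (1364 rim and 1702 interior spots) than of the KO section (761 and 1985).

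The authors' deposited table gives Moran's I for each gene, which is near 1 where neighbouring spots share a level and near 0 for a random scatter. Matrix genes led the WT section, with Col1a1 at 0.903, Col1a2 at 0.886 and Col3a1 at 0.882, followed by Arg1 at 0.836. In the KO section Gsta4, a glutathione transferase, led at 0.802, followed by the potassium channel Kcnj13 at 0.737, while Col1a1 stood at 0.734, Dct at 0.733 and Ccl8 at 0.719. Arg1 stood at 0.483 there. T cell genes were more clustered in the KO section, where Cd8a had 0.246 against 0.0239 in the WT section and Cd3e 0.340 against 0.126. All 16 pan T cell genes had the higher value in the KO section, with medians of 0.253 and 0.063. Fibroblast and matrix genes had medians of 0.502 in the KO and 0.690 in the WT section. Counting noise lowers I for sparse genes. T cell genes had fewer UMIs in the WT section, and fibroblast and matrix genes fewer in the KO section.

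Each section was clustered by itself into regions, named here by their leading genes. The WT section had 11 regions and the KO section 7. In the KO section a region led by Pvalb, Atp2a1 and Myh4, genes of fast muscle fibres, held 74 spots (2.69% of spots) and 1327 CPM of the pan T cell list, 16.4-fold the rest of the section. It held 10.6% of the section's pan T cell UMIs in 0.719% of all its UMIs. A KO region led by Cxcl14, Vcam1 and Cxcl16, of 301 spots, held 309 CPM of that list, 5.27-fold the rest. KO regions led by Capn6, Azgp1 and Gsta4 and by Selenbp1, Bnip3 and Epm2a held 29.3 and 24.1 CPM. A KO region led by Retnla, Ltc4s and Pamr1 held 28.3-fold more of the macrophage list and 18.7-fold more of the fibroblast list than the rest. In the WT section pan T cell genes were highest relative to the rest in regions led by Reg1, C1qtnf3 and Fmod (5.45-fold) and by the fat genes Cfd, Car3 and Retn (5.28-fold). Fibroblast and matrix genes stood at 108355 CPM in a WT region led by Saa3, Cxcl5 and Rbp4 and at 97651 CPM in one led by Retnla, Bmp3 and Barx2. Hypoxia genes were 3.13-fold higher in a WT region led by Npy, Ptgs2 and Mmp12, and 2.29-fold in a KO region led by Cxcl3, Crabp1 and Ccbe1, whose spots had a median of 4910 UMIs.

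**Figure D4:**
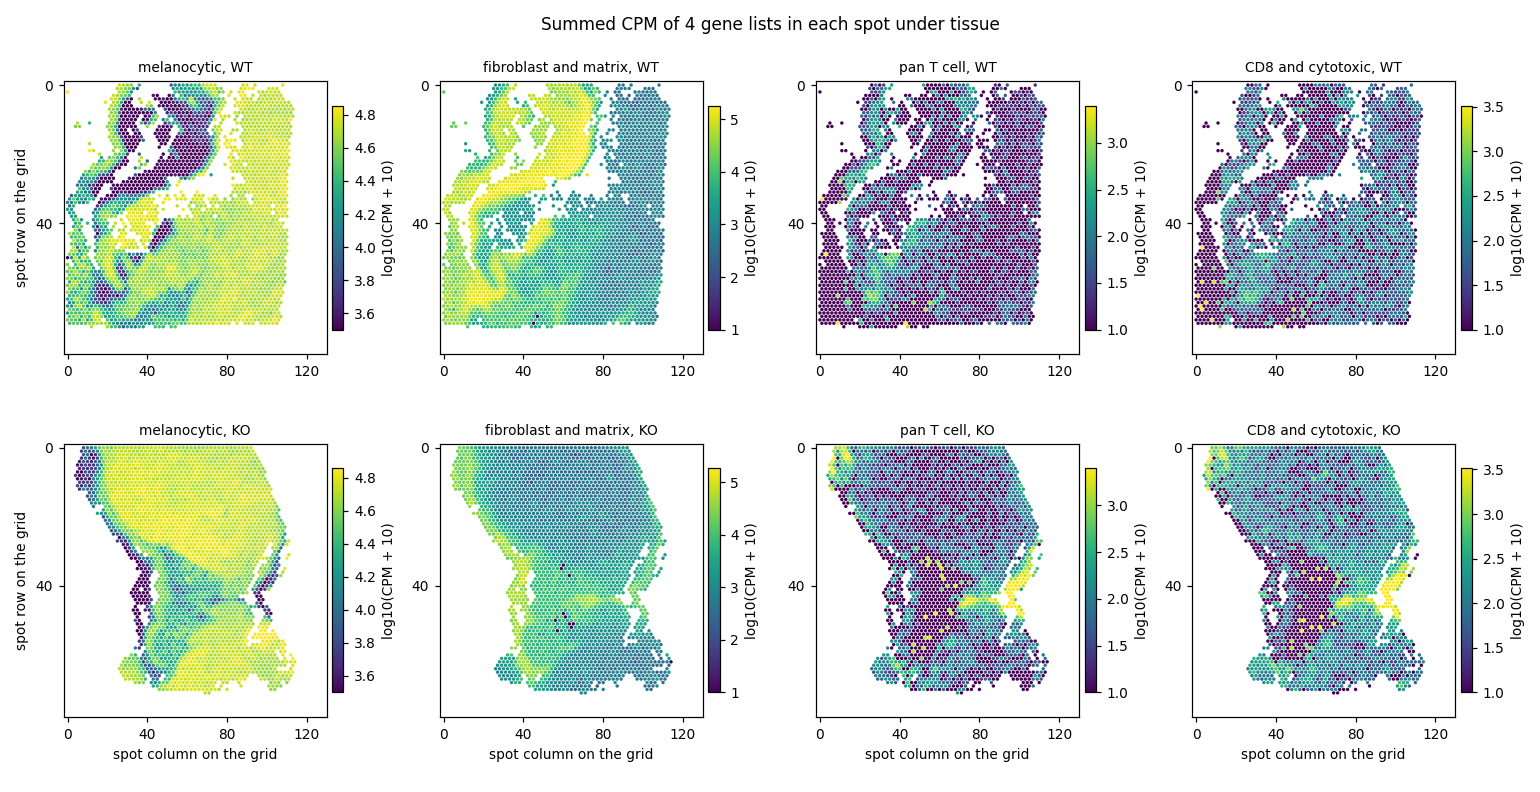
Spots under tissue placed by grid column (x) and row (y), coloured by log10(CPM + 10) of 4 gene lists, with the WT section above and the KO section below. Pan T cell colour in the KO section gathers at the edges and in a band inside the tissue (median Moran's I of 0.253 against 0.063 in the WT section), and fibroblast and matrix colour fills the upper left of the WT section.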

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

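No test of an explanation was run in this part, and the differences between sections named here were not tested, since each section is 1 library. In these results the 2 sections lie on opposite sides of a ratio of 1, each with a counting interval that leaves out 1. Rim over interior, interferon gamma response genes had a ratio of 0.832 in the WT and 1.91 in the KO section. MHC class I processing genes had 0.982 in the WT and 1.67 in the KO section. For keratinocyte genes the values were 0.915 and 1.24, and for type I interferon genes 0.968 and 1.03. The last KO value was 0.994 with a rim of 3 steps and 0.988 without the frame, so it turned. The opposite order was seen for hypoxia and glycolysis genes, with 1.16 in the WT and 0.841 in the KO section, and for Schwann cell genes, with 1.14 and 0.907. In spots with Cd8a or Cd8b1, skeletal muscle genes were at 0.0850 times the other spots in the WT section, from 2 UMIs in such spots, and at 9.60 times in the KO section.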

How the results depend on the processing

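Several settings were chosen after seeing the data. These were background subtraction, leaving out a quadrant or the KO region with the highest pan T cell CPM, and the rim without the frame. The counts of 2-fold genes under settings other than a UMI limit were chosen then too. No paired analysis was possible because each genotype has 1 section. The direction of the pan T cell, CD8 and cytotoxic, regulatory T cell, macrophage, polyamine and fibroblast list medians, and of Cd8a and Cd3e, held under every setting listed here. Of 875 values of 110 other genes, 499 stayed within the counting interval of the reported value, 370 left it, and 6 turned the direction of a gene at least 2-fold apart. Of 286 values of 26 other lists, 181 stayed, 98 left and 7 turned. A list was counted as turned only if its reported median lay outside the central 95% of its random lists, so sign changes of the other lists are among the values that stayed or left. Beside those in the report, these included MHC class I (0.01), MHC class II (0.17), melanocytic (-0.03), proliferation (-0.02) and type I interferon genes (0.20) in melanocytic-rich spots, and MHC class II (0.36) and stress genes (-0.12) with equal weight per spot. Summed CPM gave 0.22 (chemokine), -0.20 (housekeeping), -0.21 (Schwann cell) and -0.72 (keratinocyte). Where a value turned or moved, the cause was not tested, unless fewer UMIs, spots or genes by construction are named.

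TMM factors gave Csnk2b 0.858 and Cd3e 3.12, with list medians of 1.19 (pan T cell), 1.18 (CD8 and cytotoxic), -0.39 (polyamine) and -2.02 (fibroblast). Equal weight per spot gave Csnk2b 1.04 and Cd8a 1.96, with medians of 1.62 (pan T cell), 1.72 (CD8 and cytotoxic), 0.85 (regulatory T cell), -0.38 (macrophage), -0.0207 (polyamine) and -1.65 (fibroblast). Spots with at least 5000 UMIs gave a fibroblast median of -1.88.

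Interior spots gave Csnk2b 0.978, Cd8a 3.07 and Cd3e 2.89, with medians of 1.17 (pan T cell), 1.07 (CD8 and cytotoxic), -1.45 (macrophage), -0.25 (polyamine) and -2.27 (fibroblast). There the interferon gamma median turned to -0.15, the adipocyte median to 0.70 and Adipoq to 1.23. Melanocytic-rich spots gave Csnk2b 0.942 and a fibroblast median of -0.57. In them the medians of B and plasma cell (0.0446), endothelial (0.0778) and adipocyte genes (0.96) turned, as did Ccl24 (1.05), Atp2a1 (0.791), Ccl8 (0.879), Hspa1a (1.40) and Azin2 (1.04).

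Members with at least 200 UMIs gave medians of 1.77 (CD8 and cytotoxic) and 0.28 (regulatory T cell), from fewer genes. Ratios of summed CPM gave -0.38 (polyamine) and -2.52 (fibroblast), and turned interferon gamma genes to -0.0746 and adipocyte genes to 0.33. Background subtraction gave 0.0201 (regulatory T cell) and -0.24 (polyamine). Without the KO region with the highest pan T cell CPM the fibroblast median was -1.93. With 1 quadrant left out in turn, values ranged from 0.954 to 1.03 for Csnk2b, 2.90 to 5.22 for Cd8a and 2.41 to 5.47 for Cd3e. Medians ranged from 0.87 to 1.82 (pan T cell), 0.81 to 1.77 (CD8 and cytotoxic), 0.25 to 0.87 (regulatory T cell), -1.40 to -0.29 (macrophage) and -2.26 to -0.96 (fibroblast), and reached -0.12 for polyamine genes.

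Shares of spots follow the depth by construction. Cd8a was found in 0.254% of WT and 1.91% of KO spots at 2500 UMIs, 1.60% and 6.12% at 10000 UMIs, and 4.34% and 15.5% unthinned. At least 2 UMIs were found in 0 and 0.418% of spots, and 1.87% of KO interior spots had Cd8a. Any pan T cell gene was found in 9.26% and 16.6% at 2500 UMIs, 24.6% and 36.7% at 10000 UMIs, and 41.9% and 61.4% unthinned. At least 2 such UMIs were found in 4.23% and 8.996%, and 20.9% of KO interior spots had any. Of KO Foxp3 spots, 0 at 2500 UMIs and 6.67% at 10000 UMIs held Cd8a or Cd8b1. At 2500 UMIs WT spots with Cd8a or Cd8b1 had ratios of 0.462 for the CD8 and cytotoxic list and 0.872 for the interferon gamma list, both turned, with fewer UMIs.

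A rim of 1 step turned WT ratios of pan T cell (0.995), ILT3 and type 2 (0.945), checkpoint (0.975), neutrophil (0.979), melanocytic (1.07) and fibroblast genes (0.991). The KO pan T cell ratio was 2.996 with 1 step, 2.95 with 3 steps and 3.01 without the frame. The KO type I interferon ratio turned to 0.994 with 3 steps and 0.988 without the frame. With at least 200 UMIs, 162 genes were at least 2-fold higher in the KO section against 87, and with equal weight per spot 141. In melanocytic-rich spots 138 genes were at least 2-fold lower against 525. Clustering gave 7 WT regions at resolution 0.3 against 11, and 14 KO regions at resolution 1.0 against 7. Depth limits the readings of Foxp3, with 32 and 51 UMIs, and of the CD4 helper, NK cell and keratinocyte lists.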

Other observations

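The tests of explanations in this part were chosen after the results were seen. Spots with Cd8a or Cd8b1 held more of several other lists. In the WT section they held 2.24-fold more of the off-tissue background list (1.06 to 4.19), from 10 UMIs in them. At 5000 UMIs per spot the macrophage list was 1.77-fold higher in them than in other WT spots (1.64 to 1.90) and 3.08-fold in the KO section (2.95 to 3.21). Endothelial genes were 2.39-fold and 2.70-fold higher, and fibroblast and matrix genes 1.93-fold and 2.45-fold. NK cell genes were 4.75-fold higher in KO Cd8 spots (2.68 to 8.00), and rested on 2 UMIs in the WT ones. Among single genes, Cd274, which encodes the checkpoint ligand PD-L1, was 2.78-fold higher in the WT (1.42 to 4.93) and 3.28-fold in the KO section (2.42 to 4.37). The granzyme gene Gzmb was 7.62-fold and the chemokine gene Cxcl9 7.88-fold higher in KO Cd8 spots, both picked after their values were seen. In the WT section these 2 genes gave 0 and 3 UMIs in such spots. Neighbours of Cd8 spots held a pan T cell gene in 42.0% of WT and 56.8% of KO positions, against 16.0% and 23.9% around other spots.

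The list of polyamine genes ran from 1866 CPM in the WT region of 10 spots led by Myl3 and Atp2a1 to 4516 CPM in the region led by Retnla and Bmp3. In the KO section it ran from 1750.0 CPM in the region led by Pvalb and Atp2a1 to 2141 CPM in the region led by Cxcl3 and Crabp1. The muscle-led KO region, of 74 spots, also held 1533 CPM of the CD8 and cytotoxic list, a sum that mainly reads Ccl5, 10.3-fold the rest of its section. It held 21.2-fold more MHC class II and 18.4-fold more erythroid transcripts than the rest. A WT region led by S100a8 and S100a9, calprotectin genes of neutrophils, had a median of 529 UMIs per spot. It held 16.5-fold more erythroid transcripts than the rest. S100a8 and S100a9 stood at 126 and 74.5 CPM there, which is few UMIs at this depth.

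The T cell and cytotoxic lists were higher in the KO section, as were the erythroid (median log2 ratio of 2.73) and skeletal muscle lists (2.43). The median off-tissue count was higher there too, with 49 UMIs against 22 in the WT section, or 2.09-fold in CPM. The summed CPM of that list had a ratio of 1.10, but a sum leans on the largest counts. These reached 938 UMIs in the WT and 1005 in the KO section. With the median off-tissue count taken off, the CD8 and cytotoxic median log2 ratio was 1.53 (1.27 to 1.86). This covers the 12 members above 2 times the background in at least 1 section, which may be the KO section alone. Its random lists, with an upper limit of 0.36, had no such filter, so the 2 values are not compared like with like. Among interior spots the CD8 and cytotoxic median was 1.07 (0.87 to 1.36), above random lists of up to 0.67, so rim spots are not its only source. Interior spots cannot decide on neighbouring tissue caught in the section, because the skeletal muscle median was 2.75 there. In melanocytic-rich spots, where the muscle median was 0.33, the CD8 and cytotoxic median was 1.54. The erythroid median was 2.91 in these spots, so they cannot decide on blood caught in the section. The KO region with the highest pan T cell CPM, of 74 spots, held 10.6% of the section's pan T cell UMIs. Without its spots the pan T cell median was 1.28 (1.15 to 1.48), above random lists of up to 0.33. This argues against that region as the only source. The region led by Cxcl14, Vcam1 and Cxcl16, of 301 spots, was not left out in a test. Outside it the KO section held 58.5 CPM of this list, against 35.3 CPM in the WT section. An effect of the genotype is a candidate explanation. It stays open beside host sex, the plane of the section, and the neighbouring tissue and blood in it, which 1 section per genotype leaves untested.

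The fibroblast and matrix list was lower in the KO section. The difference is not the work of 1 WT quadrant alone. Without the quadrant that holds the most UMIs of this list the median was -0.96 (-1.08 to -0.95, random lists down to -0.20). With all quadrants it was -1.80, so that quadrant may still be the source of a large part of the difference. In melanocytic-rich spots the median was -0.57 (-0.77 to -0.44; random lists down to -0.22). A smaller share of stroma in the KO section's spots, from biology or from the plane of the section, may account for much of the difference. It cannot be told apart from lower expression in stroma, because a spot mixes tumour and stroma in unknown shares.

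Y-linked UMIs were found in the KO section alone. Their CPM in melanocytic-rich spots was 0.182 times that in melanocytic-poor spots (0.163 to 0.204). The KO host lists ranged from 0.110 (macrophage), 0.113 (fibroblast) and 0.195 (pan T cell) to 0.336 (CD8 and cytotoxic). Melanocytic genes had 1.58, which exceeds 1 by construction because the spots were split on this list. A candidate explanation is that the KO host was male and the WT host female. Y-linked expression in the tumour cells of the KO section alone would need a ratio of 1 or more, if melanocytic genes mark those cells. The upper bound of 0.204 argues against it under that assumption. No tumour marker outside the splitting list was used. If the hosts differed in sex, sex would differ beside genotype in every value compared between these sections.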
